A study of Homo sapiens with 6 samples.

How the data were processed

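Total RNA from MDA-MB-231 cells was sequenced 48 hours after transfection with siIGF2BP3 or siNC, with 3 libraries per group, per the labels. Libraries were made with a kit for messenger RNA sequencing, and nothing in the sources used here says whether they kept strand. The authors deposited 1 table per library with FPKM values per gene, given to 2 decimals, for 60612 genes identified by Ensembl gene IDs. The submitters' processing notes name Bowtie2 2.2.3, HISAT2 2.1.0, HTSeq 0.6.0 and the genome build hg38, without saying which tool did which step, and the tool that computed FPKM is not given in the sources used here. FPKM divides by the library total and by transcript length, so a change in a few abundant genes moves all others, and genes that overlap can share or trade fragments.

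The number of fragments per library is unknown. In genes of 60 to 110 nucleotides a step of 1 fragment was looked for only among values of 0.25 to 0.45 FPKM. The commonest value in that window was 0.30 to 0.36 FPKM per library. Of the values above 0, 61.6% to 69.4% lay below it, so it could not be taken as 1 fragment. A lower step was not looked for, and reads were not recovered. No counting interval or detection floor is therefore given. No 2 of the 6 libraries were identical. Of all genes 30679 were listed at 0 in every library, and 17 were listed at 0 in one library and at 5 FPKM or more in another. Groups and replicate numbers came from the labels. The design text of the series names siNC and siIGF2BP3 cultures and no pairing. The labels do not say how separate these cultures were, so p-values measure the spread between these samples, which may be technical.

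The plan made before the data were examined assumed counts and named a substitute for normalized values, which was used since the tables hold FPKM. Genes with a mean of at least 1 FPKM over the 6 libraries (11998) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model on group, empirical Bayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes on the log2(FPKM + 1) scale understate the change of low genes. Fold differences given as ratios are ratios of mean FPKM. The residual degrees of freedom were 4, with a prior of 2.79. Per-gene positions, exon lengths, GC content, biotypes and overlaps were taken from GENCODE release 29 on hg38, which held 11951 of the 11998 tested genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

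The replicate numbers in the labels are shared by both groups. Deviations from the group means correlated across genes at 0.60, 0.37 and 0.48 between libraries of the same number and at -0.42 to 0.04 between libraries of different numbers, so the numbers pair the samples, as a property of the data and not of a stated design. The paired test added the replicate number as a block, which leaves 2 residual degrees of freedom with a prior of 2.15. On simulated data with 50 genes per fold size among 11998, the test without the block recovered 0 of the 1.5-fold, 13 of the 2-fold, 45 of the 4-fold and 47 of the 8-fold changes, with 5 false calls. With the block it recovered 13, 28, 46 and 47, with 7 false calls.

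There were 26 gene lists with 532 entries fixed beforehand, covering the IGF2BP family, SLIT-ROBO signalling, other axon guidance genes, m6A factors, reported IGF2BP targets, epithelial and mesenchymal markers, matrix proteases, integrins and adhesion, ERK, FOXO and YAP-TEAD output, G2/M, S phase, p53 targets, interferon response, inflammatory output, unfolded protein and stress response, hypoxia and glycolysis, cholesterol synthesis, histones, mitochondrial mRNAs, and markers of fibroblast, immune, endothelial and luminal breast cells. Camera in limma tested the 24 lists with at least 3 tested members against all other tested genes, with a preset correlation of 0.01 between genes and, as an alternative, an estimated one. No list passed in any fit run with an estimated correlation. Such fits use only the residual degrees of freedom (4, or 2 with the replicate block), so few lists could pass whatever the correlation. For the G2/M list in the paired test the estimate was 0.0276, yet its unadjusted camera p went from 1.591e-10 to 0.03092. Calls lost this way are therefore not shown to come from correlation between genes. Members were also adjusted over the list alone. In the paired test 22.2% of all tested genes had an unadjusted p under 0.05, and 48.6% moved the same way in all 3 pairs. A few members past the paired test over the list alone are thus not particular to a list.

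Named genes were IGF2BP3, IGF2BP1, IGF2BP2, SLIT2 and ROBO1, then up to 10 protein-coding genes in each direction with the largest log2 fold change past the threshold, a mean log2 value of at least 1 and groups that did not overlap, and up to 4 members of each list with the smallest p (for other cell types and RNA quality, the highest means). TGFB2-OT1, TGFB2, the genes with large fold changes in the paired test and list members past the threshold only in the paired test were added after their values were seen. Some list members are not reported here. Alternatives tried were other scalings, filters, pseudocounts, variance priors, a correction of each library for a smooth trend on GC content and exon length, the replicate block, leaving out each library or replicate number, other thresholds and the rotation test fry. Leaving out 1 library leaves its replicate number in 1 group only, and those fits held no block.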

Results

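RNA was sequenced from MDA-MB-231 cells, an established triple-negative breast cancer line, 48 hours after transfection with a small interfering RNA against IGF2BP3 (siIGF2BP3) or a control small interfering RNA (siNC). IGF2BP3 is an RNA-binding protein that recognises m6A, a methyl mark on adenosines of messenger RNA. There were 3 libraries per group. The values are FPKM (fragments per kilobase of transcript, scaled to a common number of mapped fragments), which summed to between 304973 and 355767 per library. Between 11559 and 12277 genes per library had an FPKM of at least 1. The number of reads behind these values is unknown. The comparison of siIGF2BP3 with siNC asked which transcripts differed after the knockdown, and the series title points to SLIT2 as a gene of interest.

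The targeted transcript was lower in every siIGF2BP3 library than in every siNC library. IGF2BP3 (ENSG00000136231 in the files, chromosome 7, 23310209 to 23470467, minus strand, hg38, with 17.9% of its exon length overlapped by MALSU1 on the other strand) measured 3.91, 3.66 and 4.29 FPKM with siNC and 1.29, 1.07 and 1.43 FPKM with siIGF2BP3. The means were 3.95 ± 0.317 and 1.26 ± 0.181 FPKM (SD, n = 3 each), a 3.13-fold difference. On the log2(FPKM + 1) scale IGF2BP3 was lower by a log2 fold change of -1.13 (SE 0.13), and it fell when adjusted over the list alone (limma, adjusted p = 0.000133). Over all 11998 tested genes the adjusted p was 0.2002. Its paralogue IGF2BP2 measured 13.8 ± 2.80 FPKM with siNC and 11.6 ± 2.56 FPKM with siIGF2BP3 (log2 fold change -0.24, adjusted p = 0.911 over all genes). In the paired test, which takes the replicate number as a block, its adjusted p was 0.177 over all genes. Over the list alone IGF2BP2 kept its unadjusted p of 0.0193, since it had the larger p of only 2 tested members. IGF2BP1 was close to 0 in both groups (0.05 and 0.04 FPKM). The IGF2BP family list thus had 2 tested members, of which 1 fell when adjusted over the list alone and 0 changed over all genes.

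SLIT2, a secreted guidance ligand, was higher in every siIGF2BP3 library than in every siNC library. SLIT2 measured 1.89, 1.21 and 1.13 FPKM with siNC and 4.80, 2.94 and 2.89 FPKM with siIGF2BP3, a 2.51-fold difference of the means (1.41 ± 0.418 and 3.54 ± 1.09 FPKM, SD, n = 3 each). Its log2 fold change was 0.90 (SE 0.21), and was 1.00, 0.83 and 0.87 within replicate pairs 1, 2 and 3. SLIT2 was the 1 member of 8 tested in the SLIT-ROBO list that rose when adjusted over the list alone (limma, adjusted p = 0.0330, and 0.00227 with the replicate block). Over all genes its adjusted p was 0.728, and 0.136 in the paired test. The list was chosen because the series title names SLIT2, a title that may rest on these same libraries. Adjustment over the list alone may then be too lenient for SLIT2. The SLIT2 receptor gene ROBO1 averaged 0.757 ± 0.324 FPKM with siNC and 0.753 ± 0.401 FPKM with siIGF2BP3 (SD, n = 3 each), under the mean of 1 FPKM set for testing. With no filter its adjusted p was 0.999. ROBO3 went from 4.63 to 3.44 FPKM and ROBO4 from 5.51 to 3.95 FPKM, and both fell in the paired test when adjusted over the list alone (adjusted p = 0.0355 and 0.0149). ARHGAP39, a binding partner of ROBO receptors, measured 2.28 and 2.74 FPKM. As a set the SLIT-ROBO list did not pass against other genes (camera adjusted p = 0.859). It passed the mixed fry test, which counts changes in either direction (adjusted p = 0.00773). That test asks a different question, whether members changed at all, and makes no comparison with other genes. SLIT2 lies on chromosome 4 (20253260 to 20620561, plus strand) and ROBO1 on chromosome 3 (78597240 to 79767815, minus strand).

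**Figure D1:**
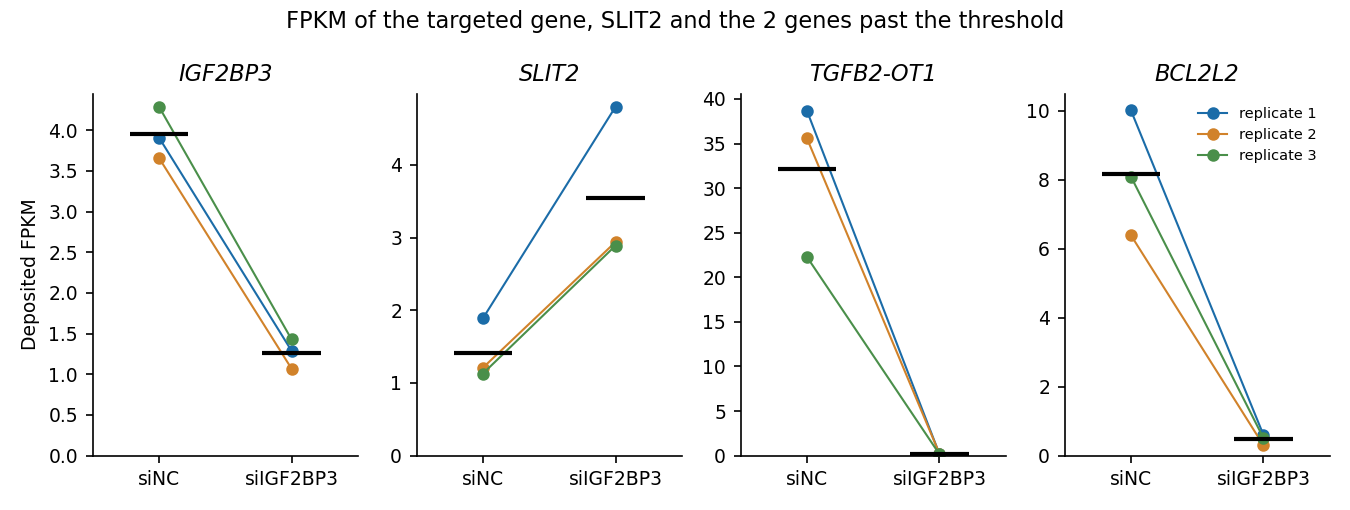
Deposited FPKM (vertical axis, linear from 0, a separate scale per panel) of IGF2BP3, SLIT2, TGFB2-OT1 and BCL2L2 in each siNC and siIGF2BP3 library. Points of one replicate number share a colour and a line, and black bars are means of 3 libraries. SLIT2 was between 1.13 and 1.89 FPKM with siNC and between 2.89 and 4.80 FPKM with siIGF2BP3.

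Across all tested genes, 2 fell and 0 rose at an adjusted p under 0.05 (limma). TGFB2-OT1 and BCL2L2 were the genes that fell, each by more than 1 on the log2 scale. TGFB2-OT1 is a non-coding transcript whose exons lie within those of TGFB2 on the same strand (chromosome 1, 218442626 to 218443996), so their reads could not be told apart with certainty. It was chosen for description after its values were seen, since it is not protein-coding. It measured 38.68, 35.58 and 22.29 FPKM with siNC and 0.17, 0.22 and 0.16 FPKM with siIGF2BP3 (log2 fold change -4.77, SE 0.21, adjusted p = 0.00151). TGFB2 itself measured 18.6 ± 3.46 and 21.6 ± 1.20 FPKM (SD, n = 3 each). BCL2L2, which encodes the anti-apoptotic protein BCL-W (chromosome 14, 23298790 to 23311759, plus strand), went from 8.16 ± 1.81 to 0.470 ± 0.154 FPKM (SD, n = 3 each), a 17.4-fold difference (log2 fold change -2.63, SE 0.18, adjusted p = 0.0149). BCL2L2 shares 24.3% of its exon length with other genes, among them the read-through gene BCL2L2-PABPN1, so its reads could not be assigned with certainty. The BCL2L2 call ended when siNC replicate 3 or any 1 of the siIGF2BP3 libraries was left out (adjusted p between 0.0640 and 0.0902, log2 fold change between -2.69 and -2.54) and when no filter was applied (adjusted p = 0.112). Without both replicate 1 libraries, or without both replicate 2 libraries, 0 genes passed (smallest adjusted p 0.167 and 0.233), and without both replicate 3 libraries 1 gene fell.

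At an unadjusted p under 0.05, 383 genes were higher and 322 lower with siIGF2BP3, 5.88% of those tested. The paired test also called 0 genes up and 2 down at an adjusted p under 0.05, but placed 1504 higher and 1161 lower at an unadjusted p under 0.05, 22.2% of those tested. The same model gave 2673 genes at that p between replicates 2 and 3. At an adjusted p under 0.2, chosen after the data were examined, the paired test gave 1126 higher and 905 lower genes, with a median absolute log2 fold change of 0.33. With median-of-ratios scaling these were 883 and 1056, so the share of higher genes was 55.4% or 45.5% depending on the scaling. With a correction for GC content and length they were 365 and 261, and with no filter 0 and 0 (smallest adjusted p 0.298). Without both libraries of replicate 1, 2 or 3 the paired test gave 0 higher genes each, and 0, 0 and 1 lower. Of all tested genes 1484 had groups that did not overlap, 12.4%, where chance gives 10.0% if the libraries are not paired.

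Among protein-coding genes in that paired set, those with large fold changes are named here after their values were seen. AHNAK, which encodes a very large scaffold protein, measured 45.34, 1.61 and 2.2 FPKM with siNC and 64.47, 51.85 and 97.95 FPKM with siIGF2BP3. Its log2 fold change was 3.26 (SE 1.05, adjusted p = 0.827), and without siNC replicate 1 it was 4.60 with an adjusted p of 0.0178. STK4, a kinase of the Hippo pathway, averaged 1.62 and 7.51 FPKM (log2 fold change 1.67, paired adjusted p = 0.134). TMEM51 averaged 3.64 and 9.86 FPKM, MIER3 1.05 and 3.68 FPKM, and PEG10, a retrotransposon-derived imprinted gene, 1.93 and 5.76 FPKM. GANAB, a catalytic subunit of glucosidase II in the endoplasmic reticulum, averaged 70.3 ± 8.16 and 139 ± 10.5 FPKM (SD, n = 3 each, log2 fold change 0.98, paired adjusted p = 0.125). Lower with siIGF2BP3 were LASP1, an actin-binding protein gene (93.55, 83.95 and 108.4 FPKM with siNC and 24.2, 19.77 and 81.97 FPKM with siIGF2BP3), TMEM120B (4.09 and 1.12 FPKM), ADNP (7.26 and 2.48 FPKM), the chemokine gene CXCL16 (7.68 and 2.96 FPKM) and EVI2A (8.05 and 3.67 FPKM). NDUFA13, a subunit gene of mitochondrial complex I that shares part of its exon length with other genes, averaged 24.1 and 9.18 FPKM. Of the genes from AHNAK to NDUFA13 none passed the adjusted p of 0.05 over all genes with all 6 libraries, and none was under 0.2 in the paired test with no filter.

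Genes of mitosis were higher with siIGF2BP3 as a group. All 24 measured members of the G2/M list had a positive log2 fold change, with a median of 0.35, and 22 were higher in all 3 replicate pairs. The list rose against other genes (camera adjusted p = 8.096e-09 with a preset correlation). With an estimated correlation between its genes (0.17) the call was lost (adjusted p = 0.847), in a form of the test with 4 degrees of freedom. The directional form of the rotation test fry did not pass for this list, with or without the block. BUB1B, a spindle checkpoint kinase, went from 6.56 ± 0.387 to 10.1 ± 0.800 FPKM, and TOP2A, which untangles DNA in dividing cells, from 35.6 ± 2.43 to 51.5 ± 2.77 FPKM (SD, n = 3 each). Both rose when adjusted over the list alone (limma, adjusted p = 0.0345), the 2 members that did so, while 0 passed over all genes. In the paired test 15 members rose when adjusted over the list alone, among them the kinetochore gene CENPF (8.50 and 13.8 FPKM), TPX2 (54.7 and 70.2 FPKM) and the mitotic cyclin gene CCNB1 (46.0 and 60.4 FPKM). The correction for GC content and length took the log2 fold change of CENPF from 0.64 to 0.51 and that of TOP2A from 0.52 to 0.43. It took BUB1B from 0.56 to 0.51, TPX2 from 0.35 to 0.34 and CCNB1 from 0.41 to 0.40. The S phase list gave 17 positive values among 24 members, a median of 0.06 and 0 members past the threshold when adjusted over the list alone (camera adjusted p = 0.799). RRM1 measured 19.6 and 23.1 FPKM and the cyclin gene CCNE1 5.29 and 3.99 FPKM. Of 16 tested members of the list of p53 targets and cell cycle inhibitors, 0 passed when adjusted over the list alone, and the list's median (0.01) and mean (-0.05) differed in sign (camera adjusted p = 0.799, downward). CDKN1A, which encodes the inhibitor p21, went from 66.2 ± 21.4 to 43.6 ± 13.1 FPKM (SD, n = 3 each) and fell in the paired test when adjusted over the list alone (adjusted p = 0.00599). GADD45B measured 11.04 and 6.577 FPKM, MDM2 1.54 and 2.14 FPKM, and BAX 23.3 and 19.3 FPKM.

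**Figure D2:**
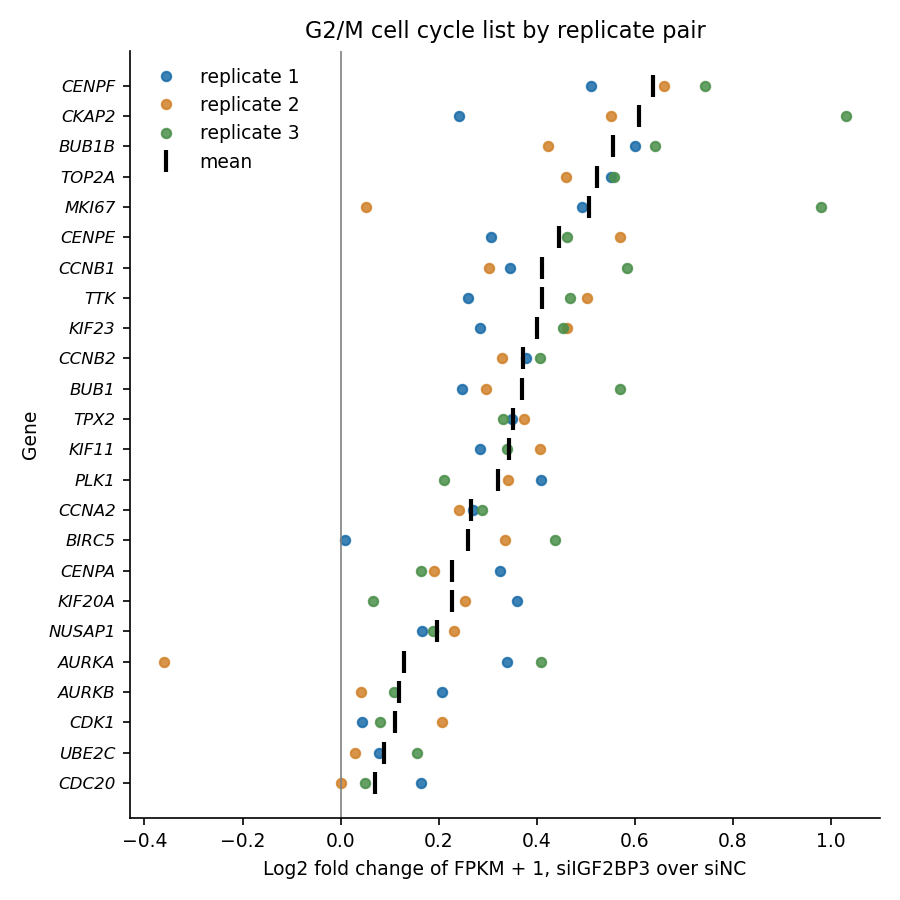
Log2 fold change of FPKM + 1, siIGF2BP3 over siNC (horizontal axis), for the 24 genes of the G2/M list (vertical axis), ordered by mean. Points are the 3 replicate pairs and black ticks their mean. All 24 means lie to the right of 0, and CENPF has the highest at 0.64.

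Several mesenchymal and matrix genes were higher with siIGF2BP3 in the paired test, and matrix proteases and their inhibitors moved both ways in it. FN1, the fibronectin gene, went from 71.3 ± 25.4 to 143 ± 53.2 FPKM (SD, n = 3 each, log2 fold change 0.99), with log2 fold changes of 1.04, 1.03 and 0.90 in the replicate pairs. FN1, ZEB1, CDH11 and VIM were the 4 of 14 tested mesenchymal markers that rose in the paired test when adjusted over the list alone (adjusted p = 0.000867 for FN1 and 0.0440 for the others). Without the block 0 did so (camera adjusted p = 0.320, upward). ZEB1, a transcription factor of the epithelial-mesenchymal transition, measured 5.11 and 6.54 FPKM, CDH11 13.7 and 24.1 FPKM, and VIM 325 and 379 FPKM. Log2 fold changes fell with GC content across genes. In the paired test the correction for GC content and length took the log2 fold change of ZEB1 from 0.31 to 0.18. It took CDH11 from 0.734 to 0.605, FN1 from 0.99 to 0.85 and VIM from 0.22 to 0.19. Among 17 tested epithelial markers 0 passed with or without the block when adjusted over the list alone (camera adjusted p = 0.873), and their median (0.02) and mean (-0.02) differed in sign. DSP measured 15.9 and 21.1 FPKM, KRT19 223 and 194 FPKM, CDH1 1.37 and 2.31 FPKM, and TJP1 4.34 and 5.11 FPKM. Of 20 tested matrix proteases and inhibitors 0 passed when adjusted over the list alone (camera adjusted p = 0.859, upward, with a median of -0.02). In the paired test 22.2% of all tested genes had an unadjusted p under 0.05. By the same adjustment as above that test gave 4 members of this list that rose and 6 that fell. ADAMTS1 (1.85 and 3.65 FPKM), MMP14 (151 and 183 FPKM) and the inhibitor gene TIMP3 (174 and 222 FPKM) were among those that rose, whereas PLAT, which encodes tissue plasminogen activator (353 and 234 FPKM), and MMP1 (222 and 151 FPKM) were among those that fell. Without siIGF2BP3 replicate 1 the log2 fold change of PLAT went from -0.61 to -0.24 and that of MMP1 from -0.67 to -0.11. That fit holds no block and leaves replicate 1 in siNC only, where both genes were lowest among the siNC libraries. Within pairs 1, 2 and 3 the values were -0.71, -0.57 and -0.55 for PLAT and -1.06, -0.59 and -0.36 for MMP1. TIMP4 measured 2.90 and 3.60 FPKM.

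Of 27 tested genes for integrins and matrix adhesion, 14 were higher and 5 lower in all 3 pairs, where 48.6% of all tested genes moved the same way. The list did not pass (camera adjusted p = 0.287, upward), and 0 members passed when adjusted over the list alone. As a set it rose without siNC replicate 3 (adjusted p = 0.00440, and adjusted p = 0.989 with an estimated correlation), while without siIGF2BP3 replicate 3 the adjusted p was 0.974. Both fits held no block, and the list was lower in replicate 1 of both groups (median log2 difference -0.16). That replicate difference adds to the group difference in them. When adjusted over the list alone, 3 members rose and 1 fell in the paired test. THBS1, the thrombospondin-1 gene, went from 64.8 to 91.4 FPKM and TNC, the tenascin-C gene, from 16.34 to 22.03 FPKM, and both were among those that rose. ITGB5 measured 27.4 and 33.6 FPKM and ITGAV 10.3 and 14.6 FPKM. In the list of other axon guidance genes, 0 of 23 passed when adjusted over the list alone (camera adjusted p = 0.950, downward, with a median of 0.00 and a mean of 0.03). In the paired test SEMA3C (11.5 and 17.6 FPKM) and its receptor gene NRP1 (12.9 and 16.8 FPKM) rose and PLXNB2 (41.7 and 31.6 FPKM) fell when adjusted over the list alone (adjusted p = 0.0387 for each). EPHA2 measured 90.5 and 73.0 FPKM, and EFNB2 11.3 and 15.4 FPKM.

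The lists for targets of the transcriptional coactivator YAP and for output of ERK signalling held both higher and lower genes, with 8 of 20 and 10 of 20 log2 fold changes positive. CCN2, a matricellular growth factor gene induced by YAP, went from 80.3 ± 7.29 to 44.1 ± 7.51 FPKM (SD, n = 3 each, log2 fold change -0.86, SE 0.16). It was the 1 of 20 members of the YAP-TEAD list that fell when adjusted over the list alone (limma, adjusted p = 0.0212, and 0.458 over all genes), and 0 rose. By that adjustment 5 members fell and 2 rose in the paired test. ANKRD1 (174 and 127 FPKM), LATS2 (5.70 and 4.22 FPKM) and AMOTL2 (10.7 and 8.29 FPKM) fell, and NT5E (84.3 and 108 FPKM) rose. As a set the YAP-TEAD list did not pass (camera adjusted p = 0.287, downward), but it fell without siNC replicate 1, siIGF2BP3 replicate 3 or both replicate 1 libraries (adjusted p = 0.01001, 0.0297 and 0.0487). With an estimated correlation these calls were lost (adjusted p = 0.854, 0.989 and 0.884). The list was also lower in replicate 1 of both groups (median log2 difference -0.38). The fits with 1 library left out held no block, so this replicate difference adds to their group difference. SPRED3, a feedback inhibitor of the ERK cascade, went from 0.753 ± 0.225 to 3.07 ± 0.556 FPKM (SD, n = 3 each, log2 fold change 1.21, SE 0.17), and was the 1 of 20 tested ERK output genes that rose when adjusted over the list alone (limma, adjusted p = 0.00400, and 0.267 over all genes). In the paired test FOSL1, an AP-1 subunit gene (92.3 and 58.9 FPKM), and the cyclin gene CCND1 (94.4 and 67.6 FPKM) fell when adjusted over the list alone (adjusted p = 0.0277 for each). HMGA1 measured 1093 and 830 FPKM. The ERK list's median (-0.00) and mean (0.02) differed in sign, with a camera adjusted p of 0.799, downward. In the FOXO list 0 of 16 tested members passed when adjusted over the list alone (camera adjusted p = 0.831). TRIB2 went from 18.2 to 24.8 FPKM and rose in the paired test when adjusted over the list alone (adjusted p = 0.0208), whereas PIK3IP1 measured 5.02 and 2.70 FPKM, CCNG2 6.35 and 5.36 FPKM, and ERBB3 1.61 and 1.27 FPKM.

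Messenger RNAs described elsewhere as IGF2BP targets showed no common shift. Of 20 tested, 8 had a positive log2 fold change, the median was -0.07 and 0 passed when adjusted over the list alone (camera adjusted p = 0.799). CCND3 measured 13.9 ± 4.03 and 8.56 ± 0.623 FPKM (SD, n = 3 each), MKI67 10.8 and 16.3 FPKM, and HMGA2 1.363 and 2.203 FPKM. CCND1 and TRIM29 (7.75 and 5.08 FPKM) were the 2 that fell in the paired test when adjusted over the list alone (adjusted p = 0.0371 and 0.0284). Without siIGF2BP3 replicate 1, in a fit without the block, the log2 fold change of TRIM29 went from -0.56 to -0.07. Within pairs 1, 2 and 3 it was -0.66, -0.54 and -0.46. For the 22 m6A writers, erasers and readers, 0 passed with or without the block when adjusted over the list alone, and 14 had positive values (camera adjusted p = 0.509). The demethylase genes ALKBH5 and FTO measured 40.3 and 33.0 FPKM and 0.910 and 1.24 FPKM, the methyltransferase gene METTL14 2.29 and 3.16 FPKM, and YTHDC2 2.62 and 3.17 FPKM.

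Genes of low oxygen response and glycolysis were more often lower with siIGF2BP3. In fits without the block, the direction of the list turned when certain single libraries were left out. Of 27 members 12 were lower and 3 higher in all 3 pairs, and the median log2 fold change was -0.16. Across all tested genes 48.6% moved the same way in all 3 pairs. The list did not pass without the block (camera adjusted p = 0.287) and fell with the replicate block (adjusted p = 0.00480). That call was lost with an estimated correlation (adjusted p = 0.878 in the paired test). The direction was upward without siNC replicate 3 or siIGF2BP3 replicate 1 (camera adjusted p = 0.923 and 0.739), whereas the list fell without siNC replicate 1 or siIGF2BP3 replicate 3 (adjusted p = 7.511e-07 and 0.00260) and without both replicate 1 libraries (adjusted p = 0.00210). These 3 calls were lost with an estimated correlation (adjusted p = 0.854, 0.989 and 0.884). The aldolase genes ALDOC (21.5 and 13.7 FPKM) and ALDOA (331 and 239 FPKM) and BNIP3L (44.8 and 37.8 FPKM) had lower means, while CA12, a carbonic anhydrase gene, was higher (13.0 ± 5.75 and 24.2 ± 3.23 FPKM, SD, n = 3 each). For this list 0 members passed with or without the block when adjusted over the list alone. The same list differed between replicate numbers, with 21 of its 27 genes lower in replicate 1 of both groups than in replicates 2 and 3. With 1 library left out, a fit without the block mixes this replicate difference into the group difference. The turns in direction therefore do not show that the list rests on single libraries. The cholesterol and lipid synthesis list had 21 of 27 genes higher in replicate 1. Between siIGF2BP3 and siNC its median log2 fold change was 0.08 and 0 members passed when adjusted over the list alone (camera adjusted p = 0.799, upward). That list rose without siNC replicate 1 or siIGF2BP3 replicate 3 (adjusted p = 9.748e-05 and 0.0290, and adjusted p = 0.854 and 0.989 with an estimated correlation), and its direction was downward without siNC replicate 3 or siIGF2BP3 replicate 1 (adjusted p = 0.166 and 0.451). The same limit holds for these turns. SC5D measured 2.70 and 4.68 FPKM, ACACA 3.99 and 5.64 FPKM, and SREBF1 10.4 and 12.7 FPKM.

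**Figure D3:**
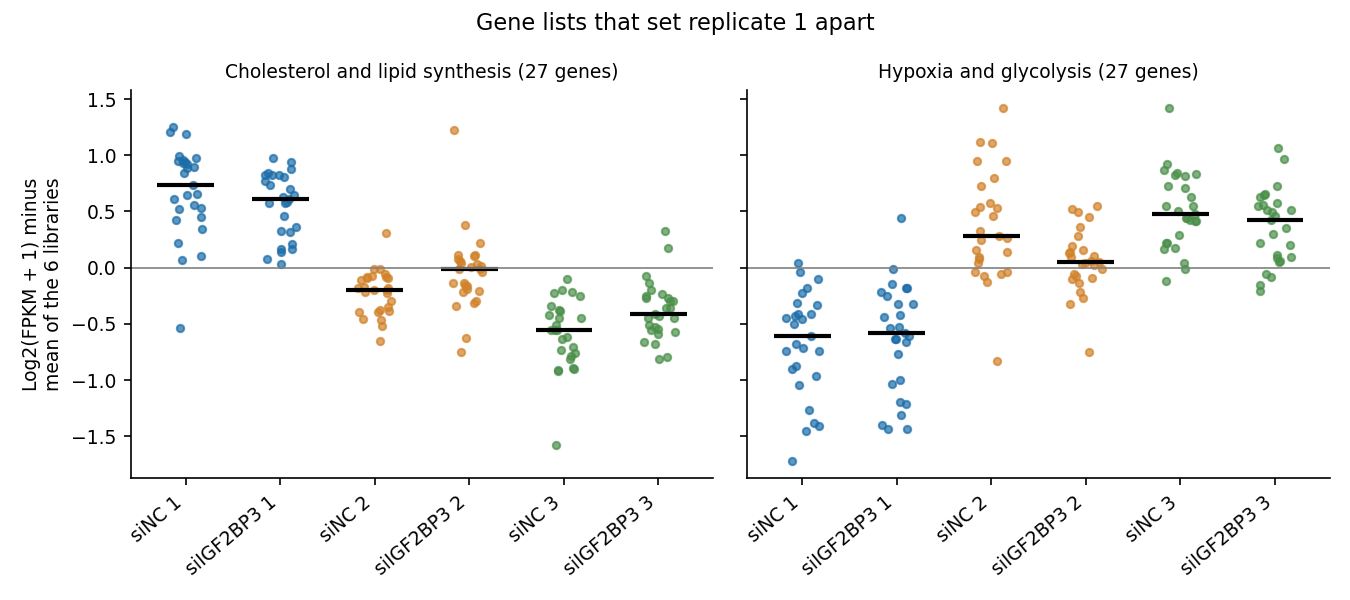
Log2(FPKM + 1) of each gene minus its mean over the 6 libraries (vertical axis) for the 27 genes of the cholesterol and lipid synthesis list and the 27 of the hypoxia and glycolysis list, by library (horizontal axis). Points are genes, coloured by replicate number, and black bars are medians. In each list 21 genes differed between replicate 1 and replicates 2 and 3.

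Of 26 tested interferon-stimulated genes, 0 passed when adjusted over the list alone (camera adjusted p = 0.799). By that adjustment 4 rose in the paired test, namely IFI44 (4.18 ± 0.699 and 7.41 ± 1.63 FPKM, SD, n = 3 each), IFIT1 (10.83 and 14.99 FPKM), IFIT3 (35.6 and 45.8 FPKM) and IFIT2 (13.7 and 17.4 FPKM). DDX60 measured 3.21 and 4.06 FPKM and IRF7 4.14 and 3.36 FPKM. Among 25 tested inflammatory cytokine and NF-kB output genes 0 passed with or without the block when adjusted over the list alone, and 0 were higher and 8 lower in all 3 pairs (camera adjusted p = 0.509, downward). Without siIGF2BP3 replicate 1 the direction of that list was upward (adjusted p = 0.451), and without siIGF2BP3 replicate 3 or both replicate 3 libraries it fell (adjusted p = 0.0114 and 0.0423, and adjusted p = 0.989 and 0.991 with an estimated correlation). These fits held no block, and the list was lower in replicate 1 (median log2 difference -0.39). NFKB2 measured 28.2 and 24.1 FPKM, the cytokine gene IL1B 48.5 and 30.1 FPKM, ICAM1 253 and 211 FPKM, and CXCL8 67.6 and 112 FPKM. In the unfolded protein and integrated stress response list 0 of 23 passed when adjusted over the list alone (camera adjusted p = 0.859). SEL1L (9.98 and 13.2 FPKM) and the cystine transporter gene SLC7A11 (1.37 and 2.50 FPKM) rose in the paired test when adjusted over the list alone (adjusted p = 0.0485 and 0.0457). SHMT2 measured 21.4 and 15.2 FPKM, DNAJB9 13.2 and 10.2 FPKM, and DNAJC3 7.80 and 9.50 FPKM.

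Lists for RNA quality and for other cell types did not pass camera between the groups with all 6 libraries. The 13 mitochondrially encoded mRNAs took between 32.89% and 40.04% of all FPKM (camera adjusted p = 0.509, downward), and 0 passed when adjusted over the list alone. Without both replicate 2 libraries that list fell (adjusted p = 0.0277, and adjusted p = 0.972 with an estimated correlation). MT-ATP6 measured 4650 FPKM in siIGF2BP3 replicate 1 and between 11317 and 17413 FPKM in the other libraries, whereas the overlapping gene MT-ATP8 measured 15583 FPKM there. Of the replication-dependent histones 6 were tested (camera adjusted p = 0.799), led by H2BC12 at 52.5 and 48.0 FPKM and H1-2 at 28.1 and 25.0 FPKM. The fibroblast list had 3 tested members, with a median of -0.03 and a mean of 0.15 (camera adjusted p = 0.943), and COL1A2 measured 1.81 and 3.64 FPKM. The endothelial list had 3 (adjusted p = 0.859), with ESAM at 46.5 and 43.0 FPKM. In the mixed fry test with the replicate block the fibroblast and endothelial lists passed (adjusted p = 0.0266 and 0.0245), as did most lists. The luminal breast list had 7 (adjusted p = 0.799), with KRT19 as above and XBP1 at 21.02 and 24.1 FPKM. The immune list had 2, too few for a set test, CD68 at 49.7 and 58.9 FPKM and CD14 at 24.0 and 12.1 FPKM. In these 5 lists 0 members passed when adjusted over the list alone without the block. In the paired test COL1A2 rose and CD14 and ROBO4 fell when adjusted over the list alone.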

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

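Scalings computed on FPKM, the GC and length correction, combinations with the replicate block, leaving out whole replicate numbers and the adjusted p of 0.2 were chosen after the data were examined. The planned tests and normalizations that need counts were not run, since the tables hold FPKM. The counts of genes were 0 higher and 2 lower with the replicate block, another pseudocount, other scalings, the correction for GC content and length, and a test against a 1.5-fold change. Genes lower numbered 1 with no filter, 1 among protein-coding genes only, 1 at an adjusted p under 0.01 and 0 with the replicate block and no filter. Leaving out libraries or replicate numbers gave 0 to 1 higher and 0 to 3 lower, and 0 lower in each such paired test, where fewer samples remain. The 1 higher, AHNAK, passed without siNC replicate 1. The lower genes numbered 1 without siNC replicate 3 or siIGF2BP3 replicate 1. At an adjusted p under 0.2 the paired test gave 1126 higher and 905 lower, 365 and 261 with GC and length correction, 883 and 1056 with median-of-ratios scaling, 0 and 0 with no filter, and 0 and 0 to 1 with a replicate number left out. Lists past the threshold, 1 with the preset correlation, numbered 0 in each fit with an estimated correlation, 2 with the replicate block, 2 with the replicate block and GC and length correction, 2 with no filter (G2/M and the IGF2BP family), and 1 to 5 with libraries left out (4 without siNC replicate 1, 2 without siNC replicate 3 and 5 without siIGF2BP3 replicate 3). The directional fry test gave 0 without and 0 with the replicate block, and its mixed test 2 (SLIT-ROBO and G2/M) and 17. With a library left out the camera direction turned for several lists that did not pass with all 6 libraries. Those fits held no block, so a difference between replicate numbers adds to the group difference. For the G2/M list the adjusted p was 0.847 with an estimated correlation, 0.742 with that and the replicate block, 0.405 with directional fry and 0.0978 with directional fry and the replicate block, within a range of 2.817e-11 to 0.9893 over all alternatives. With an estimated correlation it was 0.8543, 0.771 and 0.9893 without siNC replicates 1, 2 and 3, 0.9227, 0.965 and 0.989 without siIGF2BP3 replicates 1, 2 and 3, 0.8843, 0.9724 and 0.5498 without both libraries of replicates 1, 2 and 3, 0.6758 with no filter, and 0.9091 with the replicate block and GC and length correction. Fits with an estimated correlation use few degrees of freedom, and no other cause of these differences was tested. The log2 fold change was -1.58 to -1.07 for IGF2BP3 and 0.71 to 1.27 for SLIT2 under the alternatives run, and -3.87 to -2.48 for BCL2L2 and -6.80 to -4.62 for TGFB2-OT1. For F3, a YAP-TEAD list member among those that fell in the paired test, it was -0.79 to 0.11 with a library left out, above 0 without siIGF2BP3 replicate 1. Those fits held no block, and within pairs 1, 2 and 3 the F3 values were -0.53, -0.27 and -0.33. With all 6 libraries, the main filter and the preset correlation, the replicate block changed no call at 0.05 over all genes or lists other than that of the hypoxia and glycolysis list. The unknown number of fragments keeps counting error of low genes such as ROBO1 from being stated.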

Other observations

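All tests between replicate numbers were chosen after the libraries were seen to separate by number, and the bounds for the tests of explanations were written before their results were seen. Replicate 1 of both groups differed from replicates 2 and 3 in genes of cholesterol synthesis and of hypoxia and glycolysis, among others. In a limma test with group as a covariate, 1447 genes were higher and 1099 lower in replicate 1 at an adjusted p under 0.05, against 0 higher and 1 lower between replicates 2 and 3. At an unadjusted p under 0.05 the 2 contrasts gave 4791 and 2673 genes, so replicates 2 and 3 also differed. The first principal component, 42.9% of the variance, set the 2 replicate 1 libraries apart. Cholesterol synthesis genes rose (21 of 27, median log2 difference 1.05, camera adjusted p = 6.721e-10, and adjusted p = 0.559 with an estimated correlation), such as HMGCS1 (14.8 and 12.7 FPKM in replicate 1 of siNC and siIGF2BP3, and 3.00 to 5.18 FPKM in the other libraries) and IDI1. Genes of hypoxia and glycolysis fell (21 of 27, median -0.80, adjusted p = 9.726e-14, and adjusted p = 0.559 with an estimated correlation), such as CA9 (12.7 and 11.1 FPKM against 45.3 to 57.9 FPKM), VEGFA and NDRG1.

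Of 24 lists 12 passed between replicate 1 and the others with the preset correlation, and 0 with an estimated one. MYC measured 3.71 and 1.76 FPKM in the replicate 1 libraries and 17.6 to 25.9 FPKM in the others. TXNIP, a glucose-responsive gene in the FOXO list, measured 189 and 181 FPKM against 384 to 492 FPKM, and 10 of 16 genes of that list fell (camera adjusted p = 0.00478, and adjusted p = 0.559 with an estimated correlation). IL1A measured 4.47 and 1.52 FPKM against 23.6 to 37.1 FPKM. Interferon genes were higher in 12 of 26 cases (adjusted p = 0.00479, and adjusted p = 0.559 with an estimated correlation), among them IFIT2 (20.03 and 25.88 FPKM against 8.21 to 16.05 FPKM) and OAS2. The other lists that were lower in replicate 1 were matrix proteases (adjusted p = 0.00189), YAP-TEAD output (0.00479), inflammatory output (0.00989), integrins and matrix adhesion (0.0123) and reported IGF2BP targets (0.0295). Higher were luminal breast genes (adjusted p = 0.0198), mitochondrially encoded mRNAs (0.0264), a list for RNA quality, and S phase genes (0.0276). With an estimated correlation the adjusted p of these 8 lists was between 0.559 and 0.779.

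A trend on GC content and length between libraries is argued against as the whole source of the replicate 1 pattern, since after its removal 2731 genes differed, against 2546 before. Another breast line or cell type mixed into the replicate 1 libraries stays open. The luminal breast list had a median log2 difference of 0.74, with TFF1, TFF3, AGR2 and GATA3 higher in replicate 1, while epithelial markers had a median of -0.12, KRT19 differed by -0.01, and FOXA1 averaged at most 0.00667 FPKM in either group, so the lists moved apart and the explanation cannot be told apart from a change within the cells. No biological explanation was tested, since the design names no difference between replicate numbers.

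The paired test placed 2665 genes at an unadjusted p under 0.05, 22.2%, and 48.6% of tested genes moved the same way in all 3 pairs, where chance gives 25.0%. Between replicates 2 and 3, in the same model, 2673 genes were under that p, so such a number is not particular to the knockdown. Those replicates differ themselves, so that number does not tell what chance would give between the groups. Log2 fold changes fell with GC content (Spearman -0.339 across genes, which are not independent replicates). A GC and length trend is argued against as the whole source, since 18.1% of genes stayed under that p after its removal. Swapping the labels within pairs gave at most 351 genes, and 1 of the 4 ways, the real one, reached the real number. With 4 ways the share cannot go under 0.05, so this says nothing firmer about chance. Whether the many small differences follow from loss of IGF2BP3 or from another effect of the transfected RNA was not tested, since 1 siRNA label per group was compared.

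For the 2 genes past the threshold, 2 of the 10 splits of the 6 libraries gave as many genes, the real split with 2 and the highest other with 2. That other split kept both replicate 1 libraries together with siIGF2BP3 replicate 2, and gave 1579 genes at an unadjusted p under 0.05 against 705 for the real one, so it follows the replicate 1 pattern. The other splits that place 1 library of each pair in each group gave 0 genes each, with or without the block. In 10 splits the share cannot go under 0.05. Fragments of TGFB2-OT1 may have been assigned to the overlapping gene TGFB2 with siIGF2BP3. TGFB2 gained on average 0.446 of what the lost fragments would add (SD 0.549 over 3 pairs), with values of -0.124, 0.492 and 0.971, so this explanation cannot be told apart from a loss of the transcript. For BCL2L2 the read-through gene BCL2L2-PABPN1 gained on average -0.0185 of the amount needed (SD 0.0641), which argues against a transfer to that gene. A transfer to PPP1R3E, which overlaps BCL2L2 on the other strand, was not tested. Loss of the BCL2L2 transcript, through IGF2BP3 or through the siRNA itself, stays open as untested.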
